A study of Caenorhabditis elegans with 2 samples.

How the data were processed

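Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out by the submitters on whole Caenorhabditis elegans hermaphrodites at the late embryonic stage, 3.5 hours after synchronization by bleaching of eggs. The animals carried an integrated transgene that expresses UNC-86 fused to GFP and FLAG at its C-terminus in an unc-119 mutant background, and the chromatin was sheared by sonication and precipitated with an antibody to GFP. UNC-86 is a POU homeodomain transcription factor of the class IV (Brn-3) family that acts in the specification of several neuron classes, among them the touch receptor neurons. The 2 libraries are biological replicates 1 and 2 of a single group, per the labels.

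The deposited files hold lists of peaks and no reads. One list was made by the authors for each replicate, as the peaks and background regions that enter an irreproducible discovery rate (IDR) analysis. A list of the same kind was made from the alignments of both replicates together and is called the pooled list here, and the list of peaks past the IDR threshold is called the IDR list. A control alignment entered each peak call, per the file headers. The peak caller, the aligner, the IDR threshold and the number of reads per library are not given in the sources used here, so the depth is unknown and no interval that needs it is given. Each peak has a signal value, which the authors' peak caller gave relative to the control, and a −log10 q value, both taken from the deposited lists. The signal was used only to describe and rank peaks within a list, because its scale was set by the caller and by the depth. The −log10 q value has an upper end shared by many peaks and was used only to describe the lists. Each list was deposited in the ce10 and in the ce11 build. The ce11 lists were the main ones, since the reference sequence and the Ensembl release 115 annotation (WBcel235) are of that build, and no coordinate was converted between builds. Coordinates are given 1-based.

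The IDR peaks were compared with the replicates' lists by the distance between summits. An IDR peak counted as shared with a replicate when its summit lay within 100 bp of a summit among that replicate's 816 peaks of highest signal, which equals the length of the IDR list. Chance was taken from 1000 circular shifts of the peaks within each chromosome. Agreement in signal was given as Spearman's rho and as Pearson's r of log2 signal across IDR peaks matched in both replicates, with permutation p-values from 100000 resamples. The share of summits within 1 kb of a protein-coding transcript start was tested against 10000 random positions per chromosome with an exact binomial test. The number of peaks on each chromosome was tested against the share of protein-coding genes there with an exact binomial test. For 8 sequence patterns, the share of summit windows (100 bp to each side) with a match on either strand was compared with windows of equal width centred 500 bp to each side by Fisher's exact test. For 13 gene lists, members with an IDR summit within 2 kb of any annotated transcript start were counted against all protein-coding genes. That test was exact and stratified over 10 classes of the distance to the upstream neighbouring gene. All tests were two-sided, and the Benjamini-Hochberg procedure was applied over the patterns or over the lists. Intervals of shares are 95% Wilson intervals and cover counting error over peaks only. Peaks and genes are not independent replicates, and with 1 group no comparison between groups was made.

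Apart from the counts on chromosomes I to V, the tests, patterns and lists above were fixed before the data were examined. Of the chromosomes, only X was in that plan. The rule for named genes was also fixed then. It took the nearest protein-coding genes of the 20 IDR peaks of highest signal, up to 4 members of each list with the IDR summit of highest signal within 2 kb, and unc-86, mec-3 and unc-119 in any case. The comparison with tRNA, snoRNA, snRNA, miRNA and piRNA genes was added after the data were seen and counts summits within 300 bp of a gene's midpoint. Another 10 gene groups and a search for enriched 8-base words were added in the same way and are described under the other observations. Membership of the chemoreceptor, initiation factor and aminoacyl-tRNA synthetase groups was corrected after first counts had been seen, where symbols had matched wrongly or been missed. Of the axon guidance list, 35 of 36 symbols matched the annotation, and members were counted by gene identifier.

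Alternatives changed the distance that counts as shared, the length of the replicates' lists, the build, the windows, the backgrounds and the assignment of peaks to genes. They also used the 408 IDR peaks of highest signal, or the 816 peaks of highest signal of a single replicate in place of the IDR list. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The list test and the pattern test were first tested on simulated data. In 200 simulated lists of 60 genes among 19973 with no excess, the list test passed 0.05 in 3.5%, and in lists whose members had 4 times the odds of a peak it passed in 95% (190 of 200). Simulated genes had peaks independently and p was not adjusted, whereas neighbouring genes can share a peak. The touch receptor neuron, neurotransmitter pathway, pan-neuronal, axon guidance and cilium lists are shorter, with 13 to 35 members. The 95% does not carry over to them. The pattern test passed in 7.5% of 40 simulations without a planted site and in 40 of 40 with a site planted in 5% of windows. Summit and background windows were simulated with the same base composition, whereas in the data the summit windows were richer in GC than their flanks. These rates therefore do not carry over to the data.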

Results

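Binding of GFP-tagged UNC-86 was profiled by ChIP-seq in late embryos of a transgenic C. elegans line, in 2 biological replicates of 1 group. The ce11 IDR list held 816 peaks, the pooled list 12784, the list of replicate 1 17498 and the list of replicate 2 18470. Signal, the authors' value per peak, ran from 64.7 to 838 in the IDR list with a median of 90.9, and from 25.6 to 838 in the pooled list with a median of 31.8. The −log10 q values of the IDR peaks ran from 1.93 to 3.08. The 816 IDR peaks were the 816 peaks of highest signal in the pooled list. In the ce10 build the IDR list held 812 peaks.

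The first comparison asked how far the replicates gave the same peaks. Of the 816 IDR peaks, 79.3% (95% interval 76.4 to 81.9) lay at one of the 816 strongest peaks of replicate 1 and 77.2% (74.2 to 79.95) at one of replicate 2. Both replicates entered the IDR list, so these shares are raised by construction. The replicates are compared with each other directly below. The 20 strongest IDR peaks were all among the 816 strongest peaks of each replicate, and none ranked below 22 in replicate 1 or below 28 in replicate 2. The strongest, at III 8043781 to 8044170 between protein-coding genes, with its summit 529 bp upstream of a transcript start of K12H4.5, ranked first in both replicates. Peaks at 4 ribosomal protein genes were shared in the same way, those of rpl-3, rpl-15, rpl-35 and rpl-20. The 24 genes named for the gene lists had 23 distinct peaks, of which 13 were among the 816 strongest of both replicates. The peak closest to the transcript start of unc-86 ranked 458 in replicate 1 and 1443 in replicate 2, and the peak at daf-19, which encodes the RFX factor of ciliated neurons, ranked 738 in the IDR list and 3849 in replicate 2.

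Shifted peaks reached a mean share of 0.177% in either replicate, and at most 0.858% in replicate 1 and 0.980% in replicate 2. The 816 strongest peaks of replicate 1 and of replicate 2, compared directly, shared 60.4% (493 of 816). In 767 IDR peaks matched in both replicates, the signals correlated with a Spearman's rho of 0.619 and a Pearson's r of 0.718 on the log2 scale, each with a permutation p of 1e-05, the smallest the 100000 resamples can give. These peaks were among the strongest of the pooled list and had a match in both replicates, so unmatched peaks do not enter the correlation. Across 3790 peaks matched between the replicates' full lists, rho was 0.562 and r 0.780.

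**Figure D1:**
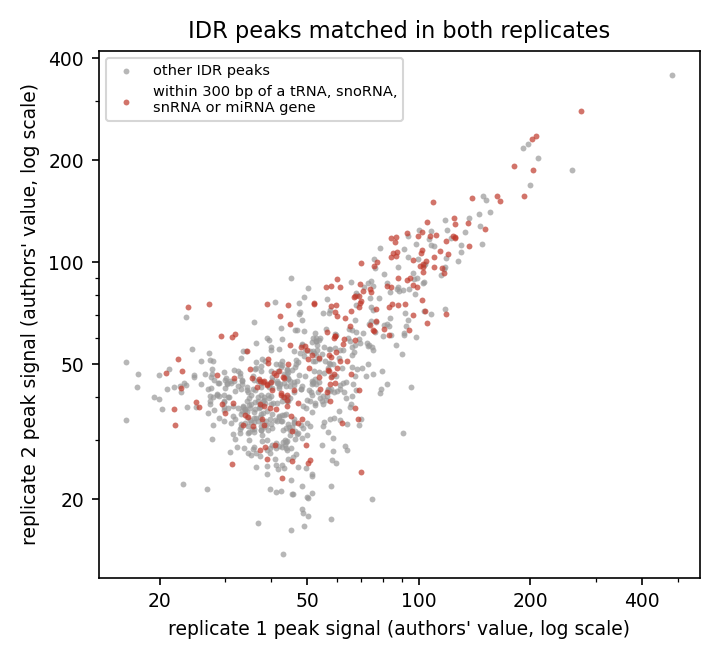
Signal of the IDR peaks that were matched in both replicates (n = 767), replicate 1 on the horizontal and replicate 2 on the vertical axis, both on log scales in the authors' signal units, 1 point per peak. Peaks within 300 bp of a tRNA, snoRNA, snRNA or miRNA gene are in red and lie at high as well as low signal, and the spread between replicates is widest among peaks of low signal (Spearman's rho 0.619 over all points).

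The second comparison asked where the IDR summits lay relative to genes. Most lay in promoter regions: 71.6% (95% interval 68.4 to 74.6) were within 1 kb of a protein-coding transcript start, against 40.4% of random positions (exact binomial p = 1.84e-72). Of these 584 summits, 506 lay upstream of the nearest start, and the median position of all 584 was 179 bp upstream. Between protein-coding genes lay 593 of the 816 summits, 72.7% against 36.2% of random positions, and 186 lay in introns. Coding exons held 9 summits, 1.10% against 24.8% of random positions. The peaks at ears-2, which encodes a glutamyl-tRNA synthetase (IV 390344 to 390645, signal 375), at tasp-1 (III 10759048 to 10759371, signal 420) and at atx-2, the ataxin-2 homolog (III 10461185 to 10461443, signal 282), had their summits 42, 101 and 74 bp upstream of a transcript start.

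Genes of small structural RNAs were frequent at the summits, in a comparison added after the data were seen. Of the 816 IDR summits, 148 (18.1%, 95% interval 15.6 to 20.9) lay within 300 bp of a tRNA gene, where shifted peaks gave a mean of 2.71 and at most 10. At snoRNA genes, whose RNAs guide the modification of ribosomal RNA, 51 summits (6.25%) were found, against a shifted mean of 1.75 and at most 8. At snRNA genes the count was 10 against a shifted mean of 0.573 and at most 4, and at miRNA genes 6 against a mean of 1.16 and at most 7 (permutation p = 0.0040). At piRNA genes, which lie mainly in clusters on chromosome IV, 5 summits were found, fewer than in any of the 1000 shifts (lowest 11). Among the 200 strongest IDR peaks, 27% were near a tRNA gene and 17% near a snoRNA gene, and among the 11968 pooled peaks outside the IDR list 1.63% and 0.451%.

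The summits lay at or near the 5' end of the tRNA genes. In the 158 tRNA genes with a summit, out of 612 annotated, the nearest summit was a median of 18 bp downstream of the gene's 5' end (interquartile range 4 to 46), and in 98 it was inside the gene, whose median length was 72 bp. Of tRNA genes with no identical copy, 23 of 143 (16.1%) had a summit. The count was 54 of 182 (29.7%) at 2 to 10 identical copies and 81 of 287 (28.2%) at over 10. None of the 20 tRNA genes without a 30-base stretch found elsewhere in the genome had one, against 158 of the other 592 (Fisher's exact p = 0.00333). How reads from repeated sequence were assigned is not given in the sources used here, so the counts at single tRNA genes are uncertain.

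Of the 20 strongest peaks, 10 were within 300 bp of a small RNA gene: 8 at snoRNA genes, 1 at a tRNA gene and 1 at mir-51. The second strongest (V 12303481 to 12303817, signal 557) lay in an intron of frm-7 beside the snoRNA genes C51F7.3 and C51F7.4, with F55C5.17 as the nearest protein-coding start. Peaks at snoRNA genes also lay nearest to W03C9.1 (II 11960650 to 11961011, signal 441), sre-23 (I 8259421 to 8259733, signal 430), str-56 (V 15873829 to 15874124, signal 391.6), T02E1.2 (I 8224270 to 8224493, signal 319), and inside pxn-1 (V 8500395 to 8500697, signal 376), cutl-18 (V 11314050 to 11314372, signal 348) and Y43F8C.7 (V 19643086 to 19643359, signal 287). The tRNA gene peak was nearest to C04A11.5 (X 13665458 to 13665701, signal 321), and the mir-51 peak to hrg-5 (IV 11026057 to 11026290, signal 277). The others lay at K12H4.5, M01F1.9 (III 3499877 to 3500187, signal 449), tasp-1, ears-2, atx-2 and the ribosomal protein genes rpl-3, rpl-15 and rpl-35, and at ftt-2, a 14-3-3 gene, where the interval X 11605676 to 11606303 was listed with 2 summits of signal 410 and 322.

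The third comparison asked how the peaks were spread over the chromosomes. Only the count on X was planned, and the tests of the other chromosomes were added to it. Chromosome III held 172 IDR peaks (21.1% against 13.2% of protein-coding genes, exact binomial adjusted p = 1.75e-09 over the chromosomes) and chromosome I 151 (18.5% against 14.4%, exact adjusted p = 0.00237). Chromosome V held 106 (13.0% against 25%, exact adjusted p = 1.86e-16). On X there were 143 peaks, 17.5% (95% interval 15.1 to 20.3) against 13.7% of protein-coding genes (exact binomial p = 0.00186, adjusted 0.00279). The X chromosome carries 45.1% of the annotated tRNA genes. Without the peaks near tRNA genes, an alternative chosen after the data were seen, X held 71 of 668 peaks, 10.6%, below its share of genes (exact p = 0.0209). Against the share of genome length on X, 17.7%, the 143 peaks were no excess (exact p = 0.963).

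The fourth comparison asked which sequence patterns marked the summits. The POU class IV site, the sequence class to which UNC-86 and its vertebrate relatives bind, was rare: it occurred in 2 of 816 summit windows (0.245%, 95% interval 0.0672 to 0.889) and in 13 of 1632 flanking windows (0.797%). The difference did not pass the test (Fisher's exact p = 0.166, adjusted 0.266 over the 8 patterns). A relaxed form of the site was in 0.858% of summit windows and 1.10% of flanks, and the octamer in 1.10% and 1.41%. The POU subsite of the mec-3 promoter type was in 35 summit windows, 4.29% against 2.76% of flanks (Fisher's exact p = 0.0532, adjusted 0.106). Without the peaks near small RNA genes, an alternative chosen after the data were seen, it was in 30 of 602 windows, 4.98% against 2.66% (Fisher's exact adjusted p = 0.0476, in a range from 0.0476 to 0.981 over the alternatives). In the 408 strongest IDR peaks it was in 2.70% against 2.94%. The E box was in 5.51% against 4.35% of flanks (Fisher's exact adjusted p = 0.301) and against 3.13% of shuffled windows (exact adjusted p = 0.0221, in a range from 0.0221 to 0.938 over the alternatives). The GAGA repeat, common at open promoters, occurred in 57 summit windows, 6.99% against 1.47% of flanks (Fisher's exact adjusted p = 5.82e-11).

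The homeodomain core TAATTA was less frequent at summits than in flanks (6.37% against 10.4%, Fisher's exact adjusted p = 0.00392), and so was the GATA site (1.35% against 3.31%, exact adjusted p = 0.0125). With other peaks, windows or flanks the homeodomain core did not pass in 5 settings, where its ratio to flanks rose from 0.612 to between 0.703 and 0.881. The GATA site did not pass in 3, at ratios of 0.385 to 0.474 about the main 0.407. Against shuffled summit windows of the same dinucleotide content neither pattern was lower (exact adjusted p = 0.546 and 0.970), and the POU class IV site stood at 0.245% against 0.184%. The summit windows had a GC content of 44.2%, their flanks 36.98%.

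The fifth comparison asked which gene lists had IDR peaks. Of all 19973 protein-coding genes, 1128 (5.65%) had an IDR summit within 2 kb of a transcript start. Ribosomal protein genes stood apart, with 31 of 76 (40.8%) where 5.61 were expected from their upstream distances, a ratio of 5.53 (exact stratified adjusted p = 2.75e-15 over the 13 lists). Their strongest peaks lay between genes, 279 bp from a start of rpl-3 (III 3867434 to 3867733, signal 408), 345 bp from rpl-15 (IV 654817 to 655069, signal 308), 430 bp from rpl-35 (III 7854582 to 7854809, signal 297) and 287 bp from rpl-20 (signal 253). Assigning each peak to its nearest transcript start alone left 14 of them, and the 408 strongest peaks left 17. This list was the single one of the 13 to pass the test.

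Neuronal lists did not pass, but most were short, and the power of the test at such lengths was not simulated. Among touch receptor neuron genes, 1 of 13 had a peak, mec-6 (signal 72.5), which encodes a subunit of the mechanosensory channel complex. Of 62 neuronal transcription factor genes, unc-86 itself was the 1 with a peak (2.23 expected). None of the 19 neurotransmitter pathway genes had one (0.883 expected), at exact adjusted p = 1. Pan-neuronal genes had 2 of 24, maco-1 (signal 68.5) and egl-21 (signal 65.2), a neuropeptide-processing carboxypeptidase (exact adjusted p = 0.601). Axon guidance genes had 4 of 35 against 1.28 expected (exact p = 0.0372, adjusted 0.242): unc-115, the ephrin receptor gene vab-1, unc-76 and the Frizzled gene lin-17, with signals from 70.1 to 72.4. Cilium genes had 3 of 25, che-13, klp-6 and daf-19 (exact adjusted p = 0.601), and neuropeptide genes 3 of 102, nlp-76, nlp-4 and flp-23 (4.31 expected, exact adjusted p = 1). All 3 neuropeptide gene peaks were within 300 bp of a small RNA gene, and that of nlp-4 was also the peak of che-13.

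Lists of other tissues did not pass either. Muscle genes had 1 of 22, unc-112 (signal 68.3), and germline genes 1 of 26, cgh-1 (signal 66.0). None of the 21 hypodermis and cuticle genes (1.04 expected) and none of the 16 intestine genes (0.791 expected) had a peak. Collagen genes had 5 of 156 against 8.77 expected (exact adjusted p = 0.601), and the 4 strongest of these peaks, at col-181, col-94, col-85 and col-185, were within 300 bp of a small RNA gene.

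**Figure D2:**
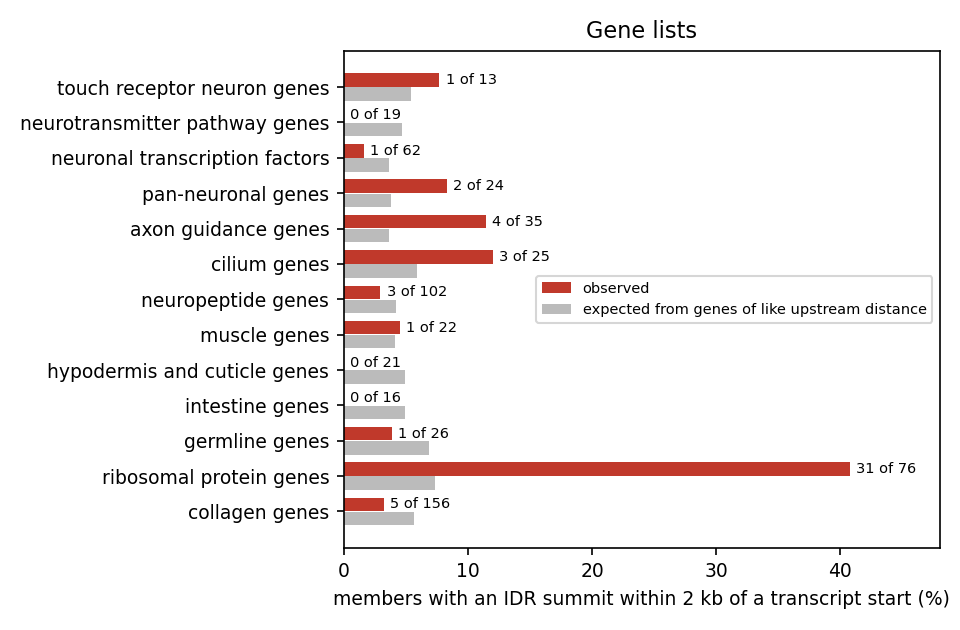
Members of each gene list with an IDR summit within 2 kb of a transcript start, in percent of the annotated members (red), and the percentage expected from protein-coding genes of like upstream distance (grey), with counts beside the bars. Ribosomal protein genes reach 40.8% (31 of 76), and no other list passed the test.

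The last comparison concerned 3 genes named in advance. At unc-86 (III 8212740 to 8216336, minus strand), 4 IDR peaks lay within 10 kb of the gene, a range added after the data were seen. One summit was in an intron (8215196, signal 72.8), 1 was 25 bp upstream of the transcript start (8216361, signal 74.4), and 2 were farther upstream (8217567, signal 71.0, and 8220303, signal 81.1). As many IDR peaks in that range were found at 10 of the 19973 protein-coding genes, in 4 distinct sets of peaks, and 3 of the 10 (unc-86, mob-4 and C30A5.16) share the peaks at unc-86. The 4 summits, in that order, ranked 607, 458, 1554 and 361 in replicate 1 and 959, 1443, 489 and 2995 in replicate 2. None was thus among the 816 strongest of both, and in replicate 2 only that at 8217567 was. Counting the 816 strongest peaks of replicate 2 themselves, 2 lay in the range, which 495 genes (2.48%) reached. None of the 4 IDR peaks was among the 408 strongest. The pooled list had 14 summits in the same range, where the median gene had 2. The mec-3 gene, a known target of UNC-86 (IV 10458816 to 10461867), had no IDR or pooled summit within 2 kb, the nearest being 19.9 kb away. Replicate 1 had a weak summit 1.05 kb away (signal 15.7, rank 10095), and the nearest of replicate 2 was 9.43 kb away (signal 17.1). At unc-119 (III 10902641 to 10908935), the wild-type form of which is the usual rescue marker in such transgenes, the nearest IDR summit was 33.5 kb away, and the pooled list had 3 summits within 2 kb, of signal up to 38.3.

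**Figure D3:**
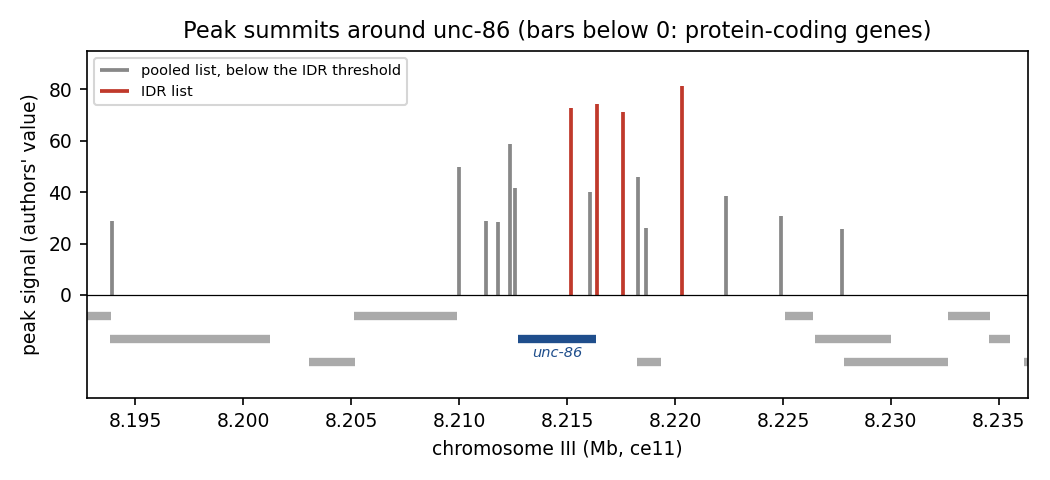
Signal (vertical axis, the authors' value) and position (horizontal axis, chromosome III, ce11, in Mb) of pooled-list summits within 20 kb of unc-86, with IDR peaks in red and the other pooled peaks in grey, and protein-coding genes as bars below 0. The 4 IDR summits, of signal 71.0 to 81.1, lie in unc-86 and upstream of it (to its right).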

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

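The comparisons with the pooled peaks outside the IDR list were chosen after those peaks had been seen. These 11968 peaks enter no main comparison, and 3 signals appeared among them. The median −log10 q value of the whole pooled list was 0.0757, so most of these entries pass no usual threshold and may be background. A POU class IV site was in 85 of their summit windows, 0.710% against 0.393% of flanking windows (Fisher's exact adjusted p = 0.000238 over the 8 patterns). It was 1 of several patterns to pass: the GAGA repeat (3.01% against 1.98%, exact adjusted p = 1.52e-08), the relaxed POU site (1.28% against 0.923%) and the mec-3 type subsite (3.07% against 2.63%) were also higher, and the GATA site (2.36% against 3.43%, exact adjusted p = 6.16e-08) and the E box (3.41% against 4.09%) lower. Of 24 pan-neuronal genes, 21 had such a summit within 2 kb where 9.13 were expected (exact stratified adjusted p = 4.93e-06 over the 13 lists). Within 300 bp of a tRNA gene lay 195 of these peaks, against at most 56 in 200 shifts. Axon guidance genes had such a summit in 25 of 35 cases (13.6 expected, exact adjusted p = 0.00065) and ribosomal protein genes in 53 of 76 (29.0 expected, exact adjusted p = 4e-07). Touch receptor neuron genes had 3 of 13 (4.85 expected), and neuropeptide genes had fewer than expected, 22 of 102 against 39.1 (exact adjusted p = 0.00102). That deficit was not found in replicate 1 beyond its 816 strongest peaks (48 against 50.1, exact adjusted p = 0.822) but was in replicate 2 (37 against 51.8, exact adjusted p = 0.0160). Collagen genes were also fewer, 44 of 156 against 58.8 (exact adjusted p = 0.0406). They did not pass with strata of the length searched per gene (exact p = 0.166, adjusted 0.359). Beyond the 816 strongest peaks of each single replicate, all 24 pan-neuronal genes had a summit in replicate 1 (11.7 expected) and 21 in replicate 2 (12.1 expected).

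The POU class IV sites and pan-neuronal genes at these weaker peaks were weighed together. Dinucleotide content as the whole cause is argued against by shuffled windows of the same content, which held the site in 0.495% of cases (Fisher's exact p = 0.00459 against 0.710%). The GAGA repeat (3.01% against 0.829%) and the E box (3.41% against 2.04%) also exceeded their shuffled shares, and the GATA site did not (2.36% against 2.34%). The E box did so while below its flanks. An excess over shuffled windows is thus particular neither to this site nor to summits. Of the related patterns, the relaxed POU site was also above its shuffled share (1.28% against 0.981%). The homeodomain core, which lies within the POU class IV site, was below its share (9.45% against 10.8%, Fisher's exact adjusted p = 1.63e-05). So were the mec-3 type subsite (3.07% against 3.53%) and the octamer (1.79% against 2.04%, exact adjusted p = 0.0906). More annotated transcript starts, and so a longer searched sequence, at pan-neuronal genes are argued against by strata of that length, where 11.9 genes were expected and 21 found (exact adjusted p = 0.000559). Binding of UNC-86 to some of these sites is consistent with the 0.710% share, a hypothesis that stays open, since other homeodomain proteins share the sequence. The share was lowest in the strongest pooled peaks, 0% in the first 200 and 0.325% (2 sites) in the rest of the first 816. In 4 bins of weaker peaks it was 0.507%, 0.95%, 0.525% and 0.815%, from stronger to weaker. It thus did not rise steadily as the signal fell, and the trend was not tested. The GC content of the windows fell from each bin to the next, to 34.8% in the weakest, and the site is rich in A and T. The shares by bin therefore cannot show whether the site set the signal. Open chromatin at these genes, whatever the tagged protein, was not tested.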

How the results depend on the processing

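The alternatives on tRNA genes, small RNA genes, searched length and the unc-86 range were chosen after the data were seen. Sharing with replicate 1 and with replicate 2 was 71.6% and 69.2% at 50 bp, 82.2% and 80.3% at 250 bp, 82.6% and 80.6% with 1 bp of overlap, 93.5% and 89.95% against 1632 replicate peaks, and 98.2% and 95.8% against full lists; wider criteria and longer lists admit more matches by construction. The X share stayed 17.5% but was no excess over genome length, was 10.6% without peaks near tRNA genes, and was 48.6% among peaks near tRNA genes, no excess over the 45.1% of tRNA genes on X; 72 of the 143 X peaks lay near tRNA genes, so fewer peaks were tested. The POU class IV share of 0.245% turned from below the flanks to above shuffled windows, as did the homeodomain core (6.37%), the GATA site (1.35%) and the relaxed POU site (0.858%). The direction also turned for the relaxed site at 50 bp (0.490%), for the octamer at 200 bp (3.06%) and without peaks near small RNA genes (1.33%), and for the mec-3 type subsite in the 408 strongest peaks (2.70%), and the cause was not tested. The homeodomain core lost its call in 5 settings, with ratios nearer 1 (0.703 to 0.881), and the GATA site in 3 at ratios about the main one (0.385 to 0.474), while the mec-3 type subsite (4.98%) and the E box (5.51%) gained one in 1 setting each. In the 408 strongest IDR peaks the direction turned for touch receptor neuron, pan-neuronal, axon guidance and muscle genes (0 members each) and for neuropeptide genes (3). It also turned for neurotransmitter pathway genes at 5 kb (2), for neuropeptide genes with nearest-start assignment (3), and for muscle genes (1) at 5 kb, without strata and by searched length; none of these lists passed the test in any setting, and the cause was not tested. Peaks within 10 kb of unc-86 numbered 0 among the 408 strongest IDR peaks. Among the 816 strongest of a single replicate, counting that replicate's own peaks, they numbered 2 to 4. Of the other 47 settings of the main comparisons, 30 had a test and kept direction and side of the threshold, 11 of them chosen after the data were seen, and 17 had no test and stayed near the main value; ribosomal protein genes passed in all 11 settings, with 14 to 33 members. Of the genes named for the lists, 9 had their peak outside the 816 strongest of a replicate. They were mec-6, unc-86, maco-1, egl-21, unc-115, vab-1, unc-76, lin-17 and daf-19, all from lists treated as neuronal above. The peak of cgh-1 had no match in replicate 2. Leaving out a replicate could not be done for the sharing or the correlation, which need both. Depth is unknown, so its limit on weak peaks cannot be given.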

Other observations

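Other gene groups were counted after the data were seen, as 10 groups defined by gene symbol, with p adjusted over the 10. Mitochondrial ribosomal protein genes had an IDR summit within 2 kb in 14 of 66 cases (4.77 expected, exact stratified adjusted p = 0.000999), proteasome subunit genes in 7 of 33 (2.46 expected, exact adjusted p = 0.0188), translation initiation factor genes in 6 of 25 (1.77 expected, exact adjusted p = 0.0166) and aminoacyl-tRNA synthetase genes in 6 of 32 (2.07 expected, exact adjusted p = 0.0249). Chemoreceptor genes, a large family expressed in sensory neurons, had 13 of 1309 (72.5 expected, exact adjusted p = 5.31e-18) and nuclear hormone receptor genes 4 of 269 (13.5 expected, exact adjusted p = 0.0142). Sm protein genes (2 of 7), V-ATPase subunit genes (3 of 20), histone genes (9 of 72) and homeobox ceh genes (1 of 63) did not pass. In the groups with an excess, the peaks of mrps-28, mrpl-23, mrps-6, rpn-8 and fars-1 were near a small RNA gene. The genes mrpl-23 and fars-1 shared a peak, as did mrps-6 and rpn-8, and mrpl-49 shared that of rpl-28. No alternative setting was run for the 10 groups.

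Enriched words of 8 bases were searched at the summits, with p adjusted over the words of each search. In the 148 windows near tRNA genes the leading word was GGGTTCGA, in 33.8% against 1.35% of flanks (Fisher's exact adjusted p = 9.17e-19), which belongs to the B box, the internal promoter element of tRNA genes. These windows were chosen for lying near tRNA genes and mostly hold their sequence. The enrichment therefore follows from the choice and says nothing about binding. In that search 681 of 4368 words passed. In the 51 windows near snoRNA genes the leading word was CTGCGCCA, in 12 windows and no flank (Fisher's exact adjusted p = 0.000319). Those windows too were chosen for lying near such genes, so this word may also follow from the choice. In the 602 windows away from small RNA genes the leading word was AAACGCGC, in 59 windows (9.80%) against 0.332% of flanks (exact adjusted p = 2.8e-20). The next was GAGACGCA, in 62 windows (10.3% against 0.914%, exact adjusted p = 1.96e-16). In that search 620 of 20741 words passed. The 602 windows had a GC content of 43.2%, against 36.98% in the flanks of all IDR summits, and base composition was not accounted for.

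All but 1 of the tests on the next patterns were chosen after the patterns were seen, the exception being the test of copies at snoRNA genes. The IDR summits at tRNA and snoRNA genes numbered 199, 24.4% of the list. Random windows of matched GC lay near such genes in 0.797% of cases, which argues against GC content as the whole cause. Any of 4 POU patterns was in 4.02% of the 199 windows (95% interval 2.05 to 7.73) and in 6.53% of their flanks. Most of these windows thus lack an exact POU pattern. Most flanks lack one too, so this says little about binding of UNC-86 to other sequence. At snoRNA genes, reads shared between copies are argued against by the 256 genes unique in the genome without such neighbours, of which 17.97% had a summit (at most 2.34% in the shifts). At tRNA genes a first test gave 16.1% in genes without an identical copy (at most 3.50% in the shifts). A stricter one devised after it found a summit in 0% of 16 unique genes. The shifts reached 12.5% there, so this few genes could hardly show an excess. The 20 unique genes together had a summit less often than the others (Fisher's exact p = 0.00333), as shared reads predict. Shared reads thus stay open at tRNA genes, and whether the unique genes are transcribed less was not tested. Recovery at genes transcribed heavily in most cells, whatever protein carries the tag, is a possible explanation in line with the 40.8% of ribosomal protein genes with a summit, and no library from an untagged strain or another tagged protein was analysed here to separate it from binding by UNC-86.

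The pooled summits around unc-86 numbered 7 in the 10 kb upstream of the gene and 5 in the 10 kb downstream, where 97.5% of random 10 kb segments held at most 5. Extra transgene copies of the unc-86 region raising the background there may be the cause: the segments 10 to 20 kb away held 1 summit each, the median of random segments, but the extent of the transgene is not given in the sources used here. UNC-86 bound directly to a POU consensus site at its own gene could be another, and 1 of the 14 summit windows within 10 kb held any of the 4 POU patterns, against 0 of 28 flanks (Fisher's exact p = 0.333). The explanations cannot be told apart with this few windows and an unknown transgene extent.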
